A study of Arabidopsis thaliana with 8 samples.

How the data were processed

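Transcript levels were measured with Affymetrix arrays of 22810 probe sets, 64 of them control probe sets, in green tissue of 4-week-old Arabidopsis thaliana plants. Plants were the Columbia wild type or abh1, a mutant of the large subunit of the nuclear cap-binding complex, which binds the cap at the start of messenger RNAs. Per the labels, they were sprayed with water (mock) or with 50 µM abscisic acid (ABA), a plant stress hormone, and collected after 4 h, and each array received RNA pooled from 3 biological replicates. There were 8 arrays in 4 groups, wild-type mock, wild-type ABA, abh1 mock and abh1 ABA, with 2 arrays per group, numbered 1 and 2 in the labels. The deposited values are MAS5 signal, on a linear scale. The series text names the Affymetrix software for this step, and its settings are not given in the sources used here.

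The 2% trimmed means of the 8 arrays lay between 500.04 and 500.05, so the signals were taken as already scaled by the authors and were not normalised again. An offset of 9.38, the 10th percentile of all values, was added before log2. Probe sets with a mean signal over all arrays of at least 115.4, the 40th percentile, were kept, which left 13652. Of all probe sets, 13513 had 1 gene symbol in the annotation used, 503 had several and 8794 were not listed; a probe set outside the list is unnamed here, not without a gene. Among the probe sets kept, 7408 had 1 gene, 271 several and 5973 none. Locus codes and gene order came from a RefSeq gene table. A gene with several probe sets was represented by the one with the highest mean signal.

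Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 8 arrays with 4 group means, so that the spread was shared between groups, leaving 4 residual degrees of freedom, and eBayes was run with an intensity trend. The comparisons taken from the fit were the ABA effect in wild type and in abh1, the abh1 effect in mock and in ABA, the abh1 effect averaged over both treatments, and the difference between the ABA effects, called the interaction. Tests were two-sided, adjusted by Benjamini-Hochberg over all probe sets kept, with a threshold of 0.05. An exact test of 2 arrays against 2 cannot give a p below 0.33, so none is reported for single genes. Differences are log2 with their standard error (SE); group signals are means with their standard deviation (SD, n = 2). The p-values measure only the spread between arrays, which may be technical, and the number of arrays limits the precision.

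The replicate numbers come from the labels, which state no pairing. Deviations of same-numbered arrays from their group means were correlated across probe sets, for each of the 6 pairs of groups, at 0.394 to 0.714 (median 0.572), above the level of 0.1 that was set for taking the numbers as a pairing. Every comparison is therefore also given with the replicate number as a term in the fit, called the replicate block, which leaves 3 residual degrees of freedom. Unless an SE is said to be with the block, it comes from the fit without the block. This holds also where an adjusted p with the block stands beside it. Each fit was tested on its own simulated data with 200 changed probe sets and with the residual spread of that fit. Only the data for the fit with the block held a difference between the replicate numbers. The fit without the block recovered 0 of 100 changes of log2 1 and 26 of 100 of log2 2, with 1 false call. The fit with the block recovered 10 and 63 of 100, with 4 false calls. These counts do not compare the fits on the same data. The fit without the block was not tested on data with a difference between the numbers.

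Before the data were examined, the comparisons, the alternatives in processing, the rule for named genes and 23 gene lists with 339 entries were fixed. Of these entries 42 had a probe set with that gene's name, 2 entries whose code and symbol pointed to different genes were left out, and 4 lists had the 3 members needed for a test. A further 21 lists were written from gene family names after the annotation had been seen and before any comparison was computed, and 19 of them were tested. From these added lists, 3 members were removed after the counts of called probe sets had been seen and before any list was tested. Lists were tested with limma's camera against the other probe sets kept, with a preset correlation of 0.01 between genes, adjusted over the fixed lists and over the added lists of a comparison. Camera was repeated with a correlation estimated for each list, and the rotation test fry was run beside it. Of 138 list tests 25 passed with the preset correlation, and 0 passed with an estimated correlation or with fry. A member past the threshold when adjusted over the list alone is counted separately.

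The rule for named genes took, in each comparison, up to 12 called probe sets in each direction with 1 gene and with every array of one group above every array of the other, and up to 4 members of each list by p. Where fewer than 5 passed, the 5 with the smallest p were taken as values. Genes named from the fit with the replicate block were chosen after the values had been seen. ABH1, CBP20, HAB1 and FLC are not analysed here, so the genotype labels were not checked through the mutated gene. Alternatives covered normalization between arrays, the offset, the filter, the variance model, the threshold, the replicate block, the arrays in the fit and leaving out each array. The replicate block together with quantile normalization was added after the data were seen. Figures were drawn with matplotlib 3.10.9.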

Results

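The data are 8 arrays from leaves of wild-type and abh1 plants, 2 arrays for each combination of genotype and treatment. The median signal was 131 to 160.5 on the 4 arrays numbered 1 and 180 to 216 on the 4 numbered 2. The 10th percentile of the signal was 6.80 to 7.94 on arrays numbered 1 and 11.5 to 12.7 on arrays numbered 2. The 3' to 5' signal ratios of the control transcripts ranged over the arrays from 1.04 to 1.73 for GAPDH, from 2.16 to 6.99 for actin and from 2.01 to 2.94 for ubiquitin, and the highest actin ratio was on wild-type mock replicate 1. Pearson correlations of log2 signal across probe sets had a median of 0.929 over the 4 pairs of arrays from the same group and 0.941 over the 12 pairs with the same number in other groups. The lowest same-group value was that of the wild-type ABA pair, at 0.859. Wild-type ABA replicate 2 correlated more with wild-type mock replicates 2 (0.958) and 1 (0.927) and with abh1 mock replicate 2 (0.948). Wild-type ABA replicate 1 correlated with wild-type mock replicate 1 at 0.914. Genes of the ABA receptors, the clade A phosphatases, the ABA kinases and transcription factors, ABA synthesis and osmolyte metabolism are not analysed here.

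The first comparison asked how wild-type leaves respond to ABA. The ABA and stress response effectors, which are dehydrins, late embryogenesis abundant (LEA) proteins and cold-regulated (COR) proteins that protect dehydrating cells, rose as a group. All 7 measured members were higher, with a mean log2 change of 2.44. The list has 26 entries, of which only these 7 were measured. LTI30, a dehydrin, had a signal of 931 ± 255 (SD, n = 2) in mock and 4462 ± 2510 in ABA, 4.45-fold higher (log2 2.15 ± 0.41, SE). AT3G02480, a LEA family gene, had 17.43 ± 18.5 and 4213 ± 5250; no fold is given, since its mock signal of 4.32 on replicate 1 lay under that array's 10th percentile of 7.156. Its log2 change with the offset was 9.18 within replicate 1 and 3.67 within replicate 2. Over both replicates it was 6.42, the largest of the 7 members, and it enters the group's mean. LEA4-5, at 32.62 ± 6.14 in mock and 1052 ± 1200 in ABA, had a log2 change of 3.92 ± 0.99, which was 5.67 within replicate 1 and 2.18 within replicate 2. COR47, a dehydrin, was 1.86-fold higher (log2 0.89 ± 0.23) and COR15A, a chloroplast protein that protects membranes in the cold, was 2.31-fold higher (log2 1.21 ± 0.42). The group's camera test gave an adjusted p of 2.69e-13, and adjusted p = 0.127 with an estimated correlation. Over all probe sets 0 of the 7 passed limma's test, and 6 of 7 passed when adjusted over the list alone, 7 with the replicate block. The mean change was 3.29 within replicate 1 and 1.58 within replicate 2, and it was 1.54 without wild-type ABA replicate 1, with the group still called.

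**Figure D1:**
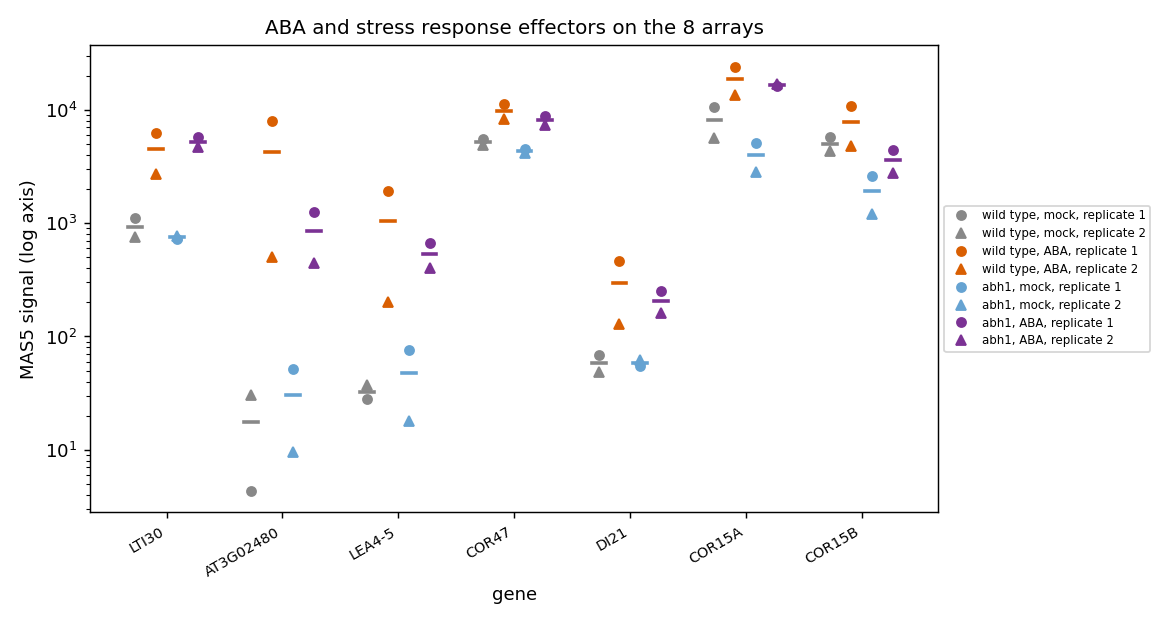
MAS5 signal (log axis) of the 7 measured ABA and stress response effectors on the 8 arrays in 4 groups; circles are replicate 1, triangles replicate 2 and short bars the group means. Every ABA array lies above the same-numbered mock array for all 7 genes in wild type and in abh1.

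Single genes in wild type were led by ZW9, 8.95-fold higher in ABA (737 ± 171 against 6897 ± 2910; log2 3.16 ± 0.37), with adjusted p = 0.376 and 0.0159 with the replicate block. The other 4 with the smallest p, each at adjusted p = 0.376, were SAG29, of the SWEET family of sugar transporters (29.06 ± 34.5 against 1507 ± 1370, with 4.69 on mock replicate 1, also under the 10th percentile, and a log2 change of 7.46 within replicate 1 and 3.13 within replicate 2), AT2G47780 8.97-fold higher, the aldehyde dehydrogenase ALDH7B4 3.43-fold higher (1675 ± 495 against 5645 ± 455), and AT3G16530 3.44-fold lower (2449 ± 351 against 702.5 ± 17.5). AT2G47780 changed by log2 4.46 within replicate 1 and 1.87 within replicate 2. EXPA8, an expansin of the family that loosens cell walls, was 7.07-fold lower (4602 ± 637 against 757 ± 576, log2 -2.82 ± 0.51). Its limma adjusted p was 0.376, and 0.0584 with the block. The log2 change of EXPA8 was -3.54 within replicate 1 and -2.11 within replicate 2. Limma called 0 probe sets, with 574 at an unadjusted p under 0.05 where chance gives 683. With the replicate block it called 1, ZW9, with 1599 at an unadjusted p under 0.05. Without the block, leaving out wild-type ABA replicate 2 gave 135.

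Among the other fixed lists in wild type, auxin response had a mean change of 1.03 and passed camera (adjusted p = 0.0215; adjusted p = 0.386 with an estimated correlation). Of its 9 entries 3 were measured. WES1, which conjugates auxin to amino acids, was 2.36-fold higher and the related GH3.3 3.65-fold higher. The auxin-induced repressor IAA29 was at log2 -0.02. None of the 3 passed limma's test when adjusted over the list alone, and 1, WES1, did with the block (0.00941). The mean was 0.69 within replicate 1 and 1.37 within replicate 2. GH3.3 passed the signal filter through wild-type ABA replicate 2, where its signal was 540 against 59.3 on replicate 1. Without GH3.3 the list would be too short to test, so the filter favoured a rise in this comparison. The list was not called without wild-type mock replicate 1 (mean 0.38) or wild-type ABA replicate 2 (mean 0.04), and the mean was 2.02 without wild-type ABA replicate 1 and 1.68 without wild-type mock replicate 2. Targets of microRNAs (5 measured of 67 entries, mean -0.27, adjusted p = 0.437) and light harvesting genes (3 measured of 25 entries, mean -0.07, adjusted p = 0.885) were not called. In fixed lists too short to test, the heat shock gene ATHSP22.0 was 2.98-fold higher (log2 1.58 ± 0.59) and the flowering gene AGL24 1.99-fold lower (log2 -0.99 ± 0.42), both at adjusted p = 0.999. ATHSP22.0 changed by log2 0.77 within replicate 1 and 2.38 within replicate 2. The median change of all probe sets was -0.09 in wild type and -0.05 in abh1, and 0.02 and 0.11 after median centring of each array.

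The second comparison asked how abh1 leaves respond to ABA. The same effectors rose as a group in abh1, with 7 of 7 higher and a mean log2 change of 2.33. LTI30 was 6.84-fold higher (746.8 ± 22.4 in mock, 5190 ± 725 in ABA; log2 2.77 ± 0.41, SE, n = 2) and COR15A 4.34-fold higher (3952 ± 1620 against 16480 ± 595; log2 2.12 ± 0.42), both with adjusted p = 0.0441 with the replicate block. LEA4-5 was 10.8-fold higher (log2 3.43 ± 0.99; 2.96 within replicate 1 and 3.90 within replicate 2) and COR47 1.86-fold, and AT3G02480 rose by log2 4.37 within replicate 1 and 4.60 within replicate 2, from a signal of 9.55 on mock replicate 2 that lay under that array's 10th percentile. Camera gave an adjusted p of 4.14e-13, and adjusted p = 0.13 with an estimated correlation. By limma 0 of the 7 passed over all probe sets and 6 of 7 adjusted over the list alone; with the block 2 and 7 did. The mean change was 2.24 within replicate 1 and 2.42 within replicate 2.

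ZW9 again had the smallest p in abh1, 12.8-fold higher in ABA (335 ± 105 against 4314 ± 43.1; log2 3.68 ± 0.37), with adjusted p = 0.15 and 0.005 with the block. The expansin EXPA16 was 8.30-fold higher (279.7 ± 16.9 against 2407 ± 411) and AT5G22460 6.09-fold higher, each at adjusted p = 0.0441 with the block, and AT2G47780 was 9.54-fold higher (0.0833 with the block). EXPA8 was 3.88-fold lower (0.107 with the block). Limma called 0 probe sets, with 576 at an unadjusted p under 0.05 where chance gives 683. With the block it called 17, of which 15 rose and 2 fell, with 1664 at an unadjusted p under 0.05; 5 of the 17 have 1 gene, and those are ZW9, EXPA16, LTI30, AT5G22460 and COR15A. Without the block the count was 12 without wild-type ABA replicate 1, 30 without wild-type ABA replicate 2 and 1 without abh1 mock replicate 2.

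Other fixed lists in abh1 were not called: auxin response had a mean of -0.17 (adjusted p = 0.787), microRNA targets -0.34 (adjusted p = 0.365) and light harvesting 0.02 (adjusted p = 0.787). GH3.3 was 2.80-fold lower in ABA in abh1 (log2 -1.49 ± 0.97) and WES1 1.61-fold higher, with adjusted p = 0.992 for each. PHV, a microRNA target that sets leaf polarity, was 2.07-fold lower (log2 -1.05 ± 0.56, adjusted p = 0.992).

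The ABA responses of the 2 genotypes come from separate arrays and were compared across probe sets. The Pearson correlation of the ABA effects was 0.665 across 13652 probe sets, which are not independent replicates, and 197 of the 200 probe sets with the smallest p went the same way. The correlation was 0.0633 without wild-type ABA replicate 1 and 0.726 without wild-type ABA replicate 2. Within replicates, the effect in wild type replicate 1 correlated with those in abh1 at 0.614 and 0.668, while wild type replicate 2 correlated with them at 0.212 and 0.144 and with wild type replicate 1 at 0.253. By limma 0 probe sets were called in both genotypes; unadjusted p under 0.05 was reached by 574 and 576 in the separate effects. With the block 1 probe set, ZW9, rose in both where 0.0011 were expected from the separate counts. The block with quantile normalization, chosen after the values were seen, gave 33 that rose in both and 4 that fell, with 0.353 and 0.00469 expected, and 21 and 4 did so without the block when wild-type ABA replicate 2 was left out.

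The next comparisons asked how abh1 differs from wild type, first averaged over both treatments. A probe set unnamed here had the smallest p, with a signal of 7207 ± 832 and 7096 ± 1190 in wild-type mock and ABA against 557 ± 47 and 710 ± 299 in abh1 (SD, n = 2), 11.4-fold lower (log2 -3.52 ± 0.23, SE). Another unnamed here was 4.90-fold lower (log2 -2.29 ± 0.21). These 2 fell and 0 rose by limma, at adjusted p = 0.0063 and 0.0385, and with the replicate block at 0.000293 and 0.0069. An unadjusted p under 0.05 was reached by 642 probe sets where chance gives 683. The count was 0 without either wild-type mock array, 1 without any 1 of the 4 abh1 arrays, and 7 without wild-type ABA replicate 2.

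With the replicate block 70 probe sets differed between abh1 and wild type, 31 higher and 39 lower in abh1, with 1555 at an unadjusted p under 0.05. Of the 70, 34 have 1 gene. AT3G48640 was 9.80-fold higher in abh1 (log2 3.29 ± 0.57; 0.00645 with the block), AT3G62960 4.34-fold (0.0204 with the block), AT3G53980 and AT1G13880 each 3.14-fold (0.00915 and 0.0069 with the block), and MSRB9, a methionine sulfoxide reductase that repairs oxidised proteins, 2.84-fold (0.032 with the block). AT3G44430 was 7.34-fold lower in abh1 (log2 -2.88 ± 0.43; 0.0069 with the block), at 454 ± 57.8 in wild-type mock and 41.9 ± 19.2 in abh1 mock. The neighbouring genes AT5G43450 and AT5G43440 were 3.73-fold and 2.27-fold lower, AT5G62360 3.63-fold, and the auxin-induced IAA29 3.25-fold (log2 -1.70 ± 0.54; 0.0221 with the block). COR15B was 2.38-fold lower (log2 -1.25 ± 0.35; 0.0221 with the block) and the cytochrome P450 gene CYP71B24 2.80-fold (0.0444 with the block). Without the block none of these named genes passed, and their adjusted p ranged from 0.0613 for AT1G13880 to 0.828 for IAA29. The SEs above also come from the fit without the block. With the block the SE was 0.245 for AT3G48640, 0.253 for AT3G44430, 0.218 for IAA29 and 0.158 for COR15B.

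**Figure D2:**
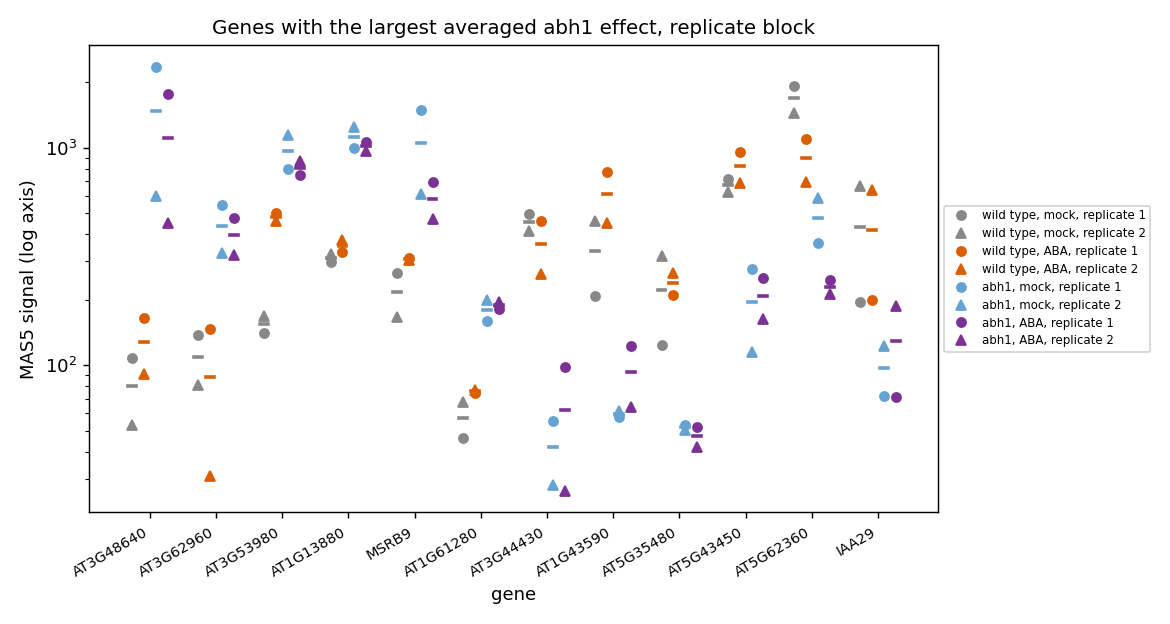
MAS5 signal (log axis) on the 8 arrays in 4 groups of 12 genes past the threshold with the replicate block for the averaged abh1 effect. They have the largest effects in each direction among called genes whose abh1 arrays all lay on the same side of wild type within both treatments. Called genes without that separation, such as CML41, are left out, so the separation was a condition of the choice. Circles are replicate 1, triangles replicate 2 and short bars the group means. AT1G13880 has mean signals of 1117 and 1014 in abh1 mock and ABA and of 311 and 354 in wild type.

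The effectors had a mean averaged abh1 effect of -0.38, with 6 of 7 lower in abh1, and passed camera (adjusted p = 0.0229; adjusted p = 0.446 with an estimated correlation). Within replicates 1 and 2 their mean was -0.0024 and -0.65 in mock and -1.05 and 0.19 in ABA. By limma 0 of the 7 passed over all probe sets and 1 of 7, COR15B, adjusted over the list alone; with the block 1 and 2 did. The group was not called after median centring (adjusted p = 0.119) and its mean was 0.07 without wild-type ABA replicate 1 and -0.83 without wild-type ABA replicate 2. It was also not called without wild-type mock replicate 1 (mean -0.36), abh1 mock replicate 2 (mean -0.20) or abh1 ABA replicate 2 (mean -0.24). Auxin response had a mean of -0.72 with 3 of 3 lower and a camera adjusted p of 0.0741. With the block it was 0.0278, and 0.449 with the block and an estimated correlation. Of the 3, 1, IAA29, passed limma's test adjusted over the list alone, without and with the block. The list could be tested only through GH3.3, which passed the signal filter through wild-type ABA replicate 2. In fixed lists with 1 or 2 measured members, the trichome patterning gene TRY was 1.61-fold higher in abh1 (log2 0.69 ± 0.20, adjusted p = 0.757) and the calmodulin-like CML38 2.77-fold lower (log2 -1.47 ± 0.47, adjusted p = 0.84). CCS, the copper chaperone of superoxide dismutase and a microRNA target, was 1.62-fold higher (log2 0.70 ± 0.26, adjusted p = 0.954). SE and DDL, which act in microRNA processing, were at log2 0.01 ± 0.39 and -0.13 ± 0.29. MicroRNA targets as a list had a mean of 0.06 (camera adjusted p = 0.821). Only 5 of the 67 entries of that list were measured, so the value says nothing about most microRNA targets.

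In mock-treated leaves alone, AT3G53980 was 5.90-fold higher in abh1 than in wild type (968 ± 243 against 154 ± 20.6, SD, n = 2; log2 2.56 ± 0.28, SE) and AT1G13880 3.497-fold higher (1117 ± 172 against 311 ± 17.2). AT3G48640 was 14.04-fold higher and AT1G57630 5.27-fold higher, and AT3G44430 9.34-fold lower. With the replicate block these 5 differed, at adjusted p = 0.0184, 0.03, 0.0184, 0.0303 and 0.0258. COR15B was 2.79-fold lower in abh1 (log2 -1.48 ± 0.49) and COR15A 2.04-fold lower (log2 -1.03 ± 0.42), each at adjusted p = 1, and the effectors as a group had a mean of -0.33 (adjusted p = 0.063; 0.03 with the block, and 0.686 with the block and an estimated correlation). Auxin response (mean -0.12), microRNA targets (0.10) and light harvesting genes (0.10) were not called, each at adjusted p = 0.764. Limma called 0 probe sets, with 398 at an unadjusted p under 0.05 where chance gives 683. With the block it called 16, of which 11 were higher and 5 lower, with 1167 at an unadjusted p under 0.05, and all 16 were among the 70 of the averaged effect.

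In ABA-treated leaves alone, AT1G13880 was 2.82-fold higher in abh1 (1014 ± 63.5 against 353.9 ± 32.6, SD, n = 2; log2 1.496 ± 0.26, SE), AT5G62360 3.71-fold lower and AT1G43590, annotated as a pseudogene, 6.09-fold lower, at adjusted p of 0.933 to 1. The effectors passed camera, with a mean of -0.43 and 6 of 7 lower (adjusted p = 0.0393; adjusted p = 0.494 with an estimated correlation), while 0 of the 7 passed limma's test adjusted over the list alone, and 1, COR15B, did with the block (0.0132). Their mean was -1.05 within replicate 1 and 0.19 within replicate 2, and it was 0.47 without wild-type ABA replicate 1, -1.33 without wild-type ABA replicate 2, -0.71 without abh1 ABA replicate 1 and -0.15, not called, without abh1 ABA replicate 2. Quantile normalization also ended this call (adjusted p = 0.104). The largest difference in the effector mean was that of AT3G02480, at log2 -1.41 ± 1.25, which was -2.66 within replicate 1 and -0.15 within replicate 2. Auxin response passed camera too, with a mean of -1.32 and 3 of 3 lower (adjusted p = 0.00187; adjusted p = 0.394 with an estimated correlation). GH3.3 had a difference of log2 -2.06 ± 0.97, which was -0.37 within replicate 1 and -3.74 within replicate 2. It was -0.56 without wild-type ABA replicate 2, where its signal was 540 against 59.3 on replicate 1. GH3.3 passed the signal filter through that array, and without GH3.3 the list would be too short to test. IAA29 was 2.93-fold lower and WES1 1.27-fold, with none of the 3 past the threshold adjusted over the list alone; with the block GH3.3 (0.0383) and IAA29 (0.00323) passed it. That list's mean was -0.56 within replicate 1 and -2.07 within replicate 2, -2.31 without wild-type ABA replicate 1 and -0.33, not called, without wild-type ABA replicate 2. Limma called 0 probe sets, with 226 at an unadjusted p under 0.05 where chance gives 683; with the block it called 1, unnamed here, with 728. The abh1 effects in mock and in ABA correlated at 0.441 across probe sets, and within replicates at 0.351 in replicate 1 and 0.0758 in replicate 2. Between the replicates the effect in mock correlated at 0.503 and the effect in ABA at -0.213.

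The last comparison asked whether the ABA response differs between the genotypes. Among the effectors COR15A had the smallest p, at log2 0.91 ± 0.59. LTI30 (0.62), COR15B (0.45) and COR47 (0.01) were also higher in abh1, and LEA4-5 (-0.49) and DI21 (-0.30) lower. The largest difference was that of AT3G02480, at -1.94 ± 1.77. Its mock signal lay under the array's 10th percentile on wild-type replicate 1 and abh1 replicate 2. With this gene included, the effectors had a mean difference between the ABA effects of -0.11, with 4 of 7 higher in abh1 and 3 lower (camera adjusted p = 0.635). That mean was 0.79 without wild-type ABA replicate 1 and -1.01 without wild-type ABA replicate 2, with the group called in both. MicroRNA targets (mean -0.07) and light harvesting genes (0.09) had adjusted p = 0.635. AT3G53980 had the smallest p: its signal was 154.4 ± 20.6 in mock and 478.3 ± 29.2 in ABA in wild type, and 968 ± 243 and 807.3 ± 82.3 in abh1 (SD, n = 2), a difference of log2 -1.82 ± 0.40 (SE). LUL1, a ubiquitin ligase, followed at log2 1.22 ± 0.34, then AT1G60590 at 1.84 ± 0.55, AT3G01560 at -1.87 ± 0.68 and AT2G22200 at -1.80 ± 0.65, each with adjusted p = 1. Limma called 0 probe sets without or with the replicate block, with 38 and 248 at an unadjusted p under 0.05 where chance gives 683. With so few small p-values the test was conservative, so 0 calls does not show that the genotypes respond alike. The median SE of the difference was 0.531, and 0.365 with the block.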

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

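The tests on wild-type ABA replicate 2 and on a single array for the chloroplast-encoded genes were chosen after those results had been seen. The other tests were set beforehand.

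In 4 gene lists the ABA effect differed between wild type and abh1 by camera on the difference itself, with 0 of the 4 kept when the correlation between genes was estimated. Auxin response had a difference of -1.2 (mean ABA effect 0.69 and 1.37 within replicates 1 and 2 of wild type, and -0.24 and -0.11 of abh1; adjusted p = 0.0417, adjusted p = 0.766 with an estimated correlation, 0.0997 with the replicate block). Its member GH3.3 went from 49.1 ± 34.5 to 299 ± 340 with ABA in wild type (SD, n = 2) and from 121.6 ± 2.08 to 37.7 ± 8.62 in abh1. Its signal of 540 on wild-type ABA replicate 2 compares with 59.3 on replicate 1. GH3.3 passed the signal filter through that array, and without GH3.3 the list would be too short to test. The call was lost without wild-type ABA replicate 2 (-0.21), wild-type mock replicate 1 (-0.55), abh1 ABA replicate 1 (-0.97), abh1 mock replicate 2 (-1.03) or abh1 mock replicate 1 (-1.37), and the value was -2.19 without wild-type ABA replicate 1 and -1.85 without wild-type mock replicate 2. Nuclear-encoded photosynthesis genes had a difference of 0.189, with 28 of 32 higher (mean ABA effect -0.25 and -0.23 within replicates 1 and 2 of wild type, and -0.17 and 0.07 of abh1; adjusted p = 0.00484, adjusted p = 0.877 with an estimated correlation). That call was lost without wild-type mock replicate 1 (0.19), abh1 mock replicate 2 (0.18), wild-type ABA replicate 2 (0.20) or abh1 ABA replicate 2 (0.08), and the value was 0.30 without abh1 ABA replicate 1. Expansins had a difference of 0.418, with 8 of 10 higher (mean ABA effect 0.07 and -0.13 within replicates 1 and 2 of wild type, and 0.41 and 0.36 of abh1; adjusted p = 0.0167, adjusted p = 0.731 with an estimated correlation). That call was lost without any 1 of the 4 abh1 arrays (0.32 and 0.51 for mock 1 and 2, 0.49 and 0.35 for ABA 1 and 2), wild-type mock replicate 2 (0.26) or wild-type ABA replicate 2 (0.47).

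Genes encoded in the chloroplast had a difference between the ABA effects of 0.725, with 59 of 66 higher (mean ABA effect -0.17 in wild type and 0.56 in abh1, where it was 0.94 within replicate 1 and 0.18 within replicate 2; adjusted p = 3.96e-07, adjusted p = 0.877 with an estimated correlation). Against wild type they were lower in abh1 mock by a mean log2 of -0.84, with 61 of 66 lower (adjusted p = 1.51e-11, adjusted p = 0.602 with an estimated correlation). An example is atpA, a subunit of the chloroplast ATP synthase, at 4085 ± 381 in wild-type mock and 1144 ± 285 in abh1 mock (SD, n = 2). In mock atpA differed by log2 -2.01 within replicate 1 and -1.69 within replicate 2. Its averaged abh1 effect passed limma's test with the replicate block (adjusted p = 0.0463). A candidate explanation for the list's lower mean is a single array, abh1 mock replicate 1. The mean was -1.30 within replicate 1, with 60 of 66 lower, and -0.38 within replicate 2, with 56 of 66 lower. The ratio of the smaller to the larger mean was 0.288, which met the bound set for a single array standing apart. That test was chosen after the result had been seen. The ratio uses both mock arrays of a replicate, so it cannot say which array stands apart. Without abh1 mock replicate 1 the mean in mock was 0.15 and the difference between ABA effects -0.27. Without the other mock arrays the mean in mock was -0.31 (wild-type replicate 2), -1.37 (wild-type replicate 1) and -1.83 (abh1 replicate 2). The difference between ABA effects was also not called without wild-type ABA replicate 1 (0.16), wild-type mock replicate 2 (0.20) or abh1 ABA replicate 2 (0.11), and it was 1.25, 1.34, 1.72 and 1.29 without wild-type mock replicate 1, abh1 ABA replicate 1, abh1 mock replicate 2 and wild-type ABA replicate 2. Leaving out 1 array leaves the numbers unequal between groups, so the difference between the numbers enters the values without an array. These values therefore cannot single out abh1 mock replicate 1, and the comparison within replicate 2 does not use that array. An effect of the abh1 mutation on chloroplast RNA stays open, since both replicates went the same way, and was not tested apart from the array.

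The effector change was smaller on wild-type ABA replicate 2, with a mean of 1.58 against 3.29 in replicate 1. This does not hold for every list called for ABA: auxin response changed by 1.37 in replicate 2 and 0.69 in replicate 1, and PUB ubiquitin ligases by 0.65 and 0.38. The auxin list could be tested only through GH3.3, which passed the signal filter through wild-type ABA replicate 2, so the filter favoured its larger change there. An array from plants that received no ABA would leave the effectors at their mock level, and 7 of 7 lay above the same-numbered mock array. A compressed intensity scale would be evened out by quantile normalization, after which the ratio of the replicate 2 to the replicate 1 change was 0.527, below the 0.8 set as the bound. As deposited, the largest gaps were those of AT3G02480 (9.18 and 3.67 within replicates 1 and 2) and LEA4-5 (5.67 and 2.18), both dim in mock. COR15A changed by 1.18 and 1.25, and the other members changed less in replicate 2. Since dim genes weigh most in the mean, the ratio cannot separate compression or background at low signal from a weaker response. A weaker or later effector response of those pooled plants stays open and was not tested, as no group of the design holds it.

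Same-numbered arrays deviated together from their group means, with a median correlation of 0.572 over 6 pairs of groups. Quantile normalization left it at 0.533, which argues against differences in the intensity distribution as the whole cause. RNA degradation cannot be told apart: the 3' to 5' ratio was higher in number 1 in 3 of 4 groups for GAPDH and for actin, and in number 2 in 4 of 4 groups for ubiquitin. The bound set beforehand used GAPDH alone and asked for 4 of 4 groups, so the 3 of 4 went against degradation by that bound. Ubiquitin went the opposite way, so the controls disagree. The question was therefore left undecided, a choice made after the values had been seen. Growth or harvest differences between the numbers stay open, and no biological explanation was tested.

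For the averaged abh1 effect, all 35 splits of the 8 arrays into 4 and 4 were fitted as a pair of groups. By the share of splits chance was not excluded: 3 of the 35, the real one included, called at least as many probe sets as the real 8. The other 2 follow known factors: the split by replicate number called 2200, the highest, which points to that structure of the samples, and the split by treatment called 83. Each of the 32 splits that follow no factor called 0, and at most 1 with the replicate block. With the replicate block, among the 18 splits balanced over the numbers, the real split called 33 and the highest other 317, which is the split by treatment, while each of the 16 that follow no factor called 0.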

How the results depend on the processing

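The replicate block with quantile normalization was chosen after the values had been seen; the other alternatives were set beforehand. For named genes, 0 values changed sign with a call as reported or in the alternative, 3832 stayed on their side of the threshold, where changes near 0 may differ in sign, and 102 newly passed it. Over the alternatives of the 138 list tests, 18 means reversed with a call as reported or in the alternative, 124 calls were lost, 71 were gained and 2397 values stayed on their side of the threshold. Counts of called probe sets rose with the replicate block, which takes the difference between arrays numbered 1 and arrays numbered 2 out of the spread: 1 for the ABA effect in wild type, 17 in abh1, 16 for the abh1 effect in mock, 1 in ABA, 70 averaged, and 1 for the overlap. With quantile normalization added to the block they were 75, 80, 26, 2, 117 and 37. No ABA effect averaged over genotypes was fitted, and the averaged abh1 effect has a median SE of 0.265 against 0.375 for each ABA effect. These counts therefore do not rank genotype against ABA. Fitted as a pair of groups, the split of the arrays by treatment called 83 probe sets and the split by genotype 8. Quantile normalization alone gave 1 for the abh1 effect in mock and 1 averaged; the cause was not tested. The averaged count was 1 with no filter, where more probe sets enter the adjustment, and 1 without the variance trend, where the cause was not tested. At an adjusted p below 0.10 it was 6, and the abh1 effect in mock 1. With only the 4 arrays compared, so with another spread, the ABA effect in abh1 gave 26 and the abh1 effect in mock 1. The interaction stayed at 0 in every alternative. Of 25 list calls, 0 were kept with an estimated correlation and 0 with fry, and 19 to 31 passed with the other settings on all arrays. Leaving out 1 array leaves the numbers unequal between groups, so the difference between the numbers enters the comparison. It gave 0 to 135 for the ABA effect in wild type, 0 to 30 in abh1, 0 to 7 for the averaged abh1 effect, 0 to 25 for the overlap and 20 to 35 list calls. The highest of the first 4 came without wild-type ABA replicate 2, and for both ABA effects and the overlap it exceeds the count with the block. The lowest averaged count came without wild-type mock replicate 1 or 2.

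List means that reversed had these ranges when 1 array was left out. For the ABA effect in wild type, ATG8 genes ran from -0.0183 to 0.981 and chloroplast-encoded genes from -0.733 to 0.40; in abh1, chloroplast-encoded genes ran from -0.435 to 1.55. For the abh1 effect in mock, chloroplast-encoded genes ran from -1.83 to 0.154 and dehydrin, LEA and COR genes from -1.21 to 0.0738. For the abh1 effect in ABA, the ranges were -1.33 to 0.468 for effectors, -0.73 to 0.501 for chloroplast-encoded genes, -0.48 to 0.0532 for UDP-glycosyltransferases, -0.391 to 0.573 for SWEET genes and -0.446 to 0.554 for ATG8 genes. For UDP-glycosyltransferases the mean was also 0.00777 with no filter, where dim members enter. Averaged over treatments, effectors ran from -0.83 to 0.0705 and chloroplast-encoded genes from -0.973 to 0.02. For the interaction, effectors ran from -1.01 to 0.794, ATG8 genes from -0.602 to 0.397, chloroplast-encoded genes from -0.269 to 1.72 and SWEET genes from -0.478 to 0.486. Signals near the 10th percentile of 9.38 leave the log2 changes of AT3G02480 and SAG29 dependent on the offset.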

Other observations

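The test for a linked chromosome segment was chosen after the called genes had been seen, and the gene families below come from lists written after the annotation had been seen. In wild type, the ATG8 genes, which build autophagosome membranes, passed camera for the ABA effect, with 9 of 9 higher and a mean log2 change of 0.48 (adjusted p = 0.0036; adjusted p = 0.752 with an estimated correlation). ATG8H was 2.26-fold higher (log2 1.18 ± 0.67, SE) and ATG8E 1.60-fold, with 0 of 9 past limma's test adjusted over the list alone, without or with the replicate block. The mean was 0.86 within replicate 1 (9 of 9 higher) and 0.11 within replicate 2 (6 of 9), -0.02 without wild-type ABA replicate 1, 0.98 without wild-type ABA replicate 2 and 0.36, not called, without wild-type mock replicate 2. In abh1 the ATG8 genes had a mean of 0.38, with 8 of 9 higher (adjusted p = 0.0535; 0.0111 with the replicate block, and 0.744 with the block and an estimated correlation). PUB ubiquitin ligases also passed camera for ABA in wild type, led by PUB19, with 5 of 6 higher and a mean of 0.52 (adjusted p = 0.0216; adjusted p = 0.658 with an estimated correlation). PUB19 was 6.10-fold higher (535.5 ± 55.7 in mock and 3772 ± 2570 in ABA, SD, n = 2) and was the only one of the 6 to pass adjusted over the list alone, without or with the block; it also passed in abh1, where it was 4.51-fold higher (306 ± 94.8 and 1382 ± 0.90). The PUB mean in wild type was 0.38 within replicate 1 (3 of 6 higher) and 0.65 within replicate 2 (6 of 6), and the call was lost without wild-type mock replicate 2 (0.53) or wild-type ABA replicate 2 (0.37). Median centring of each array ended both calls in wild type, each at adjusted p = 0.0573.

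Expansins moved with ABA in both directions in both genotypes, so that the list as a whole was not called (mean -0.03 in wild type, adjusted p = 0.856, and 0.39 in abh1, adjusted p = 0.144). EXLA1 was 3.20-fold higher in wild type and 4.54-fold in abh1, and EXLB1 2.32-fold and 2.61-fold. With EXPA16 (3.14-fold and 8.30-fold higher) and EXPA8 (7.07-fold and 3.88-fold lower), 4 of 10 expansins passed limma's test adjusted over the list alone in each genotype, and with the block 7 in wild type and 4 in abh1. Dehydrin, LEA and COR genes, 5 of whose 7 measured members are also effectors, rose with ABA by a mean of 1.35 in wild type (adjusted p = 7.27e-07; adjusted p = 0.658 with an estimated correlation) and 1.57 in abh1 (1.07e-07; adjusted p = 0.766 with an estimated correlation). Their mean within replicates 1 and 2 was 1.79 and 0.90 in wild type and 1.38 and 1.76 in abh1. It was 0.52 without wild-type ABA replicate 1 and 2.17 without wild-type ABA replicate 2 in wild type, and 0.93 without abh1 mock replicate 2 in abh1. Nuclear-encoded photosynthesis genes fell with ABA in wild type, with 25 of 32 lower and a mean of -0.24 (adjusted p = 0.0123; adjusted p = 0.752 with an estimated correlation), at -0.25 within replicate 1 and -0.23 within replicate 2. Median centring (adjusted p = 0.322) and leaving out wild-type mock replicate 1 (-0.24) or wild-type ABA replicate 2 (-0.25) ended that call.

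Nuclear-encoded photosynthesis genes were also lower in abh1 than in wild type in mock, with 28 of 32 lower and a mean of -0.23 (adjusted p = 3.92e-05; adjusted p = 0.602 with an estimated correlation), at -0.22 within replicate 1 and -0.24 within replicate 2. TAPX, a thylakoid ascorbate peroxidase, was 1.59-fold lower (log2 -0.67 ± 0.26, SE) and CHLM, an enzyme of chlorophyll synthesis, 1.34-fold lower. Neither passed limma's test adjusted over the list alone, without or with the block. In ABA the mean abh1 effect of nuclear-encoded photosynthesis genes was -0.14 within replicate 1 and 0.06 within replicate 2, with 20 of 32 higher in the latter. Their averaged abh1 effect had a mean of -0.14 (adjusted p = 0.00134; adjusted p = 0.74 with an estimated correlation), and was not called without wild-type ABA replicate 1 (-0.14), abh1 ABA replicate 1 (-0.08) or abh1 mock replicate 2 (-0.13). UDP-glycosyltransferases, which attach sugars to small molecules, had an averaged mean of -0.17, with 15 of 23 lower (adjusted p = 0.0313; adjusted p = 0.74 with an estimated correlation), and it was not called without wild-type mock replicate 1 (-0.17), abh1 mock replicate 1 (-0.10), abh1 ABA replicate 1 (-0.08) or wild-type ABA replicate 2 (-0.04), with -0.31 and -0.27 without wild-type ABA replicate 1 and abh1 ABA replicate 2. UGT85A5 was 1.79-fold lower (log2 -0.84 ± 0.20; 0.0642 with the block). PUB ubiquitin ligases passed camera for the abh1 effect in ABA, with 5 of 6 lower and a mean of -0.42 (adjusted p = 0.046; adjusted p = 0.849 with an estimated correlation), at -0.28 within replicate 1 (3 of 6 lower) and -0.56 within replicate 2 (5 of 6), a call lost without either wild-type mock array (-0.42 each), wild-type ABA replicate 1 (-0.56) or 2 (-0.27), or abh1 ABA replicate 2 (-0.43). Dehydrin, LEA and COR genes were lower in abh1 in mock, with 6 of 7 lower and a mean of -0.57 (adjusted p = 0.0201; adjusted p = 0.602 with an estimated correlation), at -0.31 within replicate 1 and -0.82 within replicate 2, but the mean was 0.07 without abh1 mock replicate 2, -0.18, not called, without wild-type mock replicate 1, -1.21 without abh1 mock replicate 1 and -0.95 without wild-type mock replicate 2, and median centring ended the call (adjusted p = 0.14).

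Called genes that cluster on a chromosome could mark a segment that differs between the lines for reasons other than abh1. Among 33 genes with a place in the gene order that passed for the averaged abh1 effect with the replicate block, the most on any 1 chromosome was 11, on chromosome 3. A single linked segment lies on 1 chromosome, so this argues against 1 such segment as the source of most of the 33. Among the 33, 1 pair lay within 20 genes of each other. Random draws gave a median of 0 such pairs and a 95th percentile of 2 (permutation p = 0.48), so no clustering beyond random draws was seen at that distance. Segments behind part of the 33 stay open, as does the place of the 36 passing probe sets that are unnamed here. The other passing probe set without a place in the order is atpA, which is encoded in the chloroplast.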
